A study of Mus musculus with 12 samples.

How the data were processed

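RNA was measured in 12 samples of mouse blood neutrophils, 6 from the control bone marrow transplant group and 6 from the group named LOY, for loss of the Y chromosome in the transplanted blood-forming cells. Per the labels' protocols, 10000 Ly6G-positive, CD115-negative, RFP-positive cells were sorted for each sample after red cell lysis, cDNA was made and amplified with SMART-Seq v4, and libraries were made with Nextera XT. This kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart. The labels do not say whether each library came from a separate mouse, so p-values measure only the spread between these libraries.

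The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and the builds GRCm38 and mm10. The authors deposited 1 table of 11494 genes with a normalized signal per gene and library, and its unit is not named in the file headers. The values of each library were whole multiples of 1 step within a tolerance of 0.02 reads, for 100.0% of values above 0 in every library, so the deposited signal is a gene read count divided by 1 size factor per library. Recovered reads per library ranged from 13743581 to 19616066. The table also holds the authors' log2 fold changes and the authors' unadjusted and adjusted p-values, per the file headers. The tool that made this comparison is not given in the sources used here. Genes with a mean below 8.63 normalized reads were not listed, so this is not a table of all annotated genes. A spreadsheet had turned 16 gene names into dates, and these were replaced through their identifiers. Of the listed identifiers, 11475 were found in GENCODE vM21 (GRCm38), which gave chromosomes and coordinates.

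Because the signal is normalized, the main test was limma 3.58.1 in R 4.3.3 (linear model with a trended, robust empirical Bayes step) on log2(value + 1). Genes with a value of 10 or more in at least 6 libraries were tested, which left 9742 genes, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and exceeds the fold of the means where some libraries of 1 group lie at or near 0. The design had no covariate, because the labels give no batch and the groups share no replicate number. The total of the Y-linked list over the library total was compared by an exact permutation test of the difference in means, two-sided, over 924 splits (scipy 1.17.1), for which the smallest possible p is 0.00216. Of 29 gene lists, 25 had 5 or more tested members and were compared by camera with a preset correlation of 0.01, with camera at an estimated correlation and fry beside it.

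The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes all tested members of the Y-linked list, the list of their X-linked homologues and the pseudoautosomal list. It adds the top 10 genes per direction past the threshold, or the next by p up to 5 per direction, the members of each list with the smallest p up to 4, and the 2 most abundant members of each list for another cell type. Genes outside the rule are named as such.

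The alternatives were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, quantile and TMM normalization, no filter, a mean of 50 or more, pseudocounts of 0.5 and 5, other thresholds, 1 surrogate variable (sva 3.50.0), sample weights, lists without shared or called members, and each library left out in turn. Chosen after seeing the data were a mean of 500 or more, the share of genes at 0 as a covariate, the libraries of Control 1, 2 and 12 left out together, edgeR without the library of Control 6, and 2 other member choices for the Y-linked total.

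The scripts were tested on simulated counts for 11494 genes with the means and library sizes of this comparison. In these counts 200 genes, drawn from those with a mean of 50 or more, were changed. At 2-fold, 4-fold and 16-fold changes limma recovered 25.4%, 47.8% and 78.8% of changed genes, edgeR 25.4%, 44.8% and 77.3%, and DESeq2 41.8%, 65.7% and 93.9%. These rates do not cover the 1693 tested genes with a mean under 50. Ndufaf1 and Clec12b, named below, are among those genes. Among the genes called were unchanged ones, 6 of 107 for limma, 2 of 100 for edgeR and 71 of 205 for DESeq2. In the same simulation camera called 1 list when 1, that of the ribosomal proteins, was shifted and 0 when none was. Simulated genes were drawn independently, whereas the estimated correlation of the erythroid list, for example, was 0.516. The simulation therefore does not show how often camera calls lists of correlated genes. Independent draws also give no excess of genes at 0 shared across a whole library. The libraries of Control 1, 2 and 12 had 20.5%, 21.7% and 17.3% of listed genes at 0. Neither the recovery rates nor the counts of unchanged genes called cover a comparison with such libraries.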

Results

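Blood neutrophils were compared between mice that had received control bone marrow and mice that had received LOY marrow, with 6 libraries in each group. The series title places the comparison in a study of haematopoietic loss of the Y chromosome, cardiac fibrosis and heart failure. Recovered reads ranged from 13743581 to 18459792 in the control libraries and from 17097739 to 19616066 in the LOY libraries. Listed genes at 0 made up 20.5%, 21.7% and 17.3% of the table in the libraries of Control 1, 2 and 12, against 9.3% to 11.1% in the other 3 control libraries and 6.6% to 11.6% in the LOY libraries (exact permutation test between groups, two-sided p = 0.0368, adjusted p = 0.141 over 5 library measures). Spearman correlations between libraries ranged from 0.759 to 0.919 across genes, which are not independent replicates. Among the libraries other than Control 1, 2 and 12 the lowest correlation was 0.858. Between Control 1, 2 or 12 and any other library the highest was 0.859.

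The Y-linked genes show whether the libraries carry the loss named in their labels. Ddx3y, an RNA helicase gene (chromosome Y, 1260771 to 1286629, GRCm38), stood at 1054 ± 267 normalized reads in the control libraries and 68.7 ± 146 in the LOY libraries (SD, n = 6 each). Eif2s3y, which encodes a translation initiation factor subunit (chromosome Y, 1010543 to 1028847), stood at 2348 ± 590 and 180 ± 396 normalized reads in the same groups. The total of the Y-linked list fell by 201 per 1000000 normalized reads, from 217 ± 44.4 to 15.9 ± 34.5, and was lower in all 6 LOY libraries than in any control library (exact permutation test, two-sided p = 0.00216, the smallest it can give). The library of LOY 4 kept 39.8% of the control mean, that of LOY 5 kept 3.10%, and the other 4 LOY libraries kept between 0.0746% and 0.573%. Of the 4 Y-linked list members in the table, 2 were tested, and both passed when adjusted over the list alone (limma, adjusted p = 0.000176 for each). Over all genes tested neither passed, with log2 fold changes of −6.65 ± 1.19 (SE) for Ddx3y (limma adjusted p = 0.189) and −7.26 ± 1.38 for Eif2s3y (adjusted p = 0.214). Without the library of LOY 4 both passed, at an adjusted p of 0.0073.

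Other chromosome Y genes were read less evenly. Uty, a histone demethylase gene related to Kdm6a, ranged from 0 to 597 normalized reads in the control libraries and from 0 to 70.4 in the LOY libraries (exact permutation test, two-sided adjusted p = 0.12). Kdm5d, a histone H3 lysine demethylase gene, was above 0 only in the libraries of Control 6 and 12, at 38.3 and 175 normalized reads, and was at 0 in all 6 LOY libraries, where a count of 0 allows up to 3 reads per library (counting error only). The processed pseudogene Gm4017 lies within the coordinates of Ddx3y. Sequences were not compared, so the source of its reads is uncertain. It stood at 49.95 ± 33.2 and 7.14 ± 3.68 normalized reads, with 4 reads in LOY 10, where Ddx3y had 0. Ddx3y and Eif2s3y have close X-linked relatives, and the counting could have split shared reads, so counts of a few reads in LOY libraries are uncertain.

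**Figure D1:**
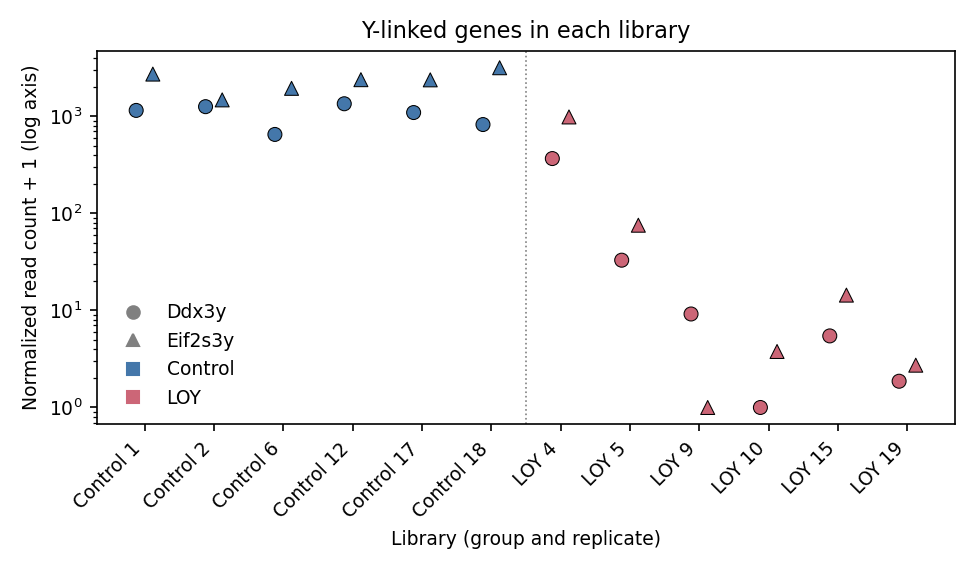
Normalized read counts plus 1 (log axis) of Ddx3y (circles) and Eif2s3y (triangles) in each of the 12 libraries, control in blue and LOY in red. LOY 4 stands at 366 for Ddx3y and 986 for Eif2s3y, below every control library and above the other LOY libraries.

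The X-linked homologues of Y genes were compared because their partners are lost with the chromosome. Of the 10 members tested 0 passed, over all genes or adjusted over the list alone (limma), and 0 had an unadjusted p under 0.05. Estimates were positive for 7 and negative for 3 with limma, and positive for 3 and negative for 7 with edgeR and with DESeq2. In these tools Rbmx (−0.26 and −0.28) and Zrsr2 (−0.04 and −0.05) were below 0. Eif2s3x stood at 57.3 ± 53.5 normalized reads in control and 109 ± 73.3 in LOY libraries (log2 fold change 1.47 ± 0.98 SE), Ddx3x at 1735 ± 783 and 1393 ± 363 (−0.27 ± 0.26), and Kdm6a at 535 ± 325 and 435 ± 166 (−0.13 ± 0.44). Kdm5c (−0.15 ± 0.22), Uba1 (0.16 ± 0.20), Rps4x (0.22 ± 0.44) and Usp9x (0.00 ± 0.46) lay within 1 SE of 0, as did Rbmx (0.88 ± 1.10) and Zrsr2 (0.80 ± 1.11), while Zfx stood at 1.36 ± 0.97. Zfx was at 0.38 without Control 2, −0.01 with 1 surrogate variable and −0.24 with the share of genes at 0 as a covariate, chosen after seeing the data, and the authors' deposited log2 fold changes were 0.48 for Zfx and 0.93 for Eif2s3x. The list did not stand apart from other genes (camera adjusted p = 0.926). None of the 5 pseudoautosomal list members was in the table.

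Across 9742 genes, 2 rose and 0 fell in LOY neutrophils (limma, adjusted p under 0.05). Ndufaf1, an assembly factor of respiratory complex I (chromosome 2, 119655446 to 119662827), rose from 0.358 ± 0.878 to 55.9 ± 49.9 normalized reads (log2 fold change 5.23 ± 0.67 SE, limma adjusted p = 0.0278). Clec12b, a C-type lectin receptor gene (chromosome 6, 129375515 to 129385874), rose from 0.515 ± 0.851 to 41.4 ± 27.7 (4.77 ± 0.64, adjusted p = 0.0278). Both were higher in 6 of 6 LOY libraries than in any control library, and both were at 0 in most control libraries, 5 of 6 for Ndufaf1 and 4 of 6 for Clec12b. At an unadjusted p under 0.05 there were 588 genes, 429 higher and 159 lower, beside a median gene that lay 0.136 above 0 on the log2 scale; with quantile normalization that median was 0.000623 and the split was 345 higher and 281 lower. With edgeR the split was 142 higher and 146 lower (median −0.00993), and with the share of genes at 0 as a covariate, chosen after seeing the data, it was 153 and 132 (median −0.0389).

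The calls depended on the tool and on single libraries. With edgeR on the recovered reads 0 genes passed (288 at an unadjusted p under 0.05), and with DESeq2 54 did, 44 higher and 10 lower, the same number as in the authors' deposited table, with all 54 shared. Of those 54 genes 26 had every library of 1 group at 0 and 43 were below the filter of the limma test. The limma count was 17 without Control 6, 7 without Control 18, 6 without LOY 15, 5 without Control 12 or LOY 4, 3 without LOY 5, 1 without Control 1 or 17, and 0 without Control 2, LOY 10 or LOY 19, and also 0 without Control 1, 2 and 12 together. Ndufaf1 and Clec12b both missed the threshold without Control 2, Control 17, LOY 9, LOY 10 or LOY 19 (limma adjusted p from 0.0515 to 0.133), and Clec12b also without Control 1 (0.0888). With 1 library left out the log2 fold changes stayed between 4.87 and 5.51 for Ndufaf1 and between 4.49 and 5.00 for Clec12b. With quantile normalization they were 3.43 and 2.97 (limma adjusted p = 0.74 for each), and with edgeR 6.935 and 6.063. Without Control 1, 2 and 12 they were 5.51 and 4.68.

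The next genes by p did not pass in the main test and are given as values. Tnfrsf12a, the receptor of the cytokine TWEAK, stood at 4.70 ± 11.5 and 92.9 ± 27.8 normalized reads in control and LOY libraries (log2 fold change 5.68 ± 0.89 SE, limma adjusted p = 0.0937), and was above 0 in 1 of 6 control libraries. Snhg5 stood at 5.04 ± 0.91 and Mrps10, a mitochondrial ribosomal protein gene, at 4.07 ± 0.74 (adjusted p = 0.189 for each). Without Control 6, the only control library with Tnfrsf12a reads, limma adjusted p was 0.00145 for Tnfrsf12a and 0.0266 for Snhg5. Over all alternatives run the adjusted p of each reached 0.9999. On the lower side were the zinc transporter gene Slc39a4 (1670 ± 193 and 1097 ± 184 normalized reads, log2 fold change −0.61 ± 0.14), the cytokine subunit gene Ebi3 (2211 ± 348 and 1505 ± 153, −0.55 ± 0.13) and the transcription factor gene Stat4 (1181 ± 416 and 527 ± 170, −1.16 ± 0.29). Stat4 was lower in 6 of 6 LOY libraries than in any control library. Ankrd11 (−0.40 ± 0.11) and the cannabinoid receptor gene Cnr2 (−0.55 ± 0.15) followed. In the authors' deposited table the adjusted p was 0.00747 for Mrps10, 0.0185 for Snhg5, 0.0212 for Slc39a4, 0.028 for Ebi3 and 0.0319 for Stat4, against 0.313 for Tnfrsf12a, 0.161 for Ankrd11 and 0.135 for Cnr2.

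Precision differed with level. For the 3582 genes with a mean of 500 or more the median SE was 0.243 and 72.4% had a 95% interval of the log2 fold change within 2-fold in either direction, whereas for the 6160 genes below that mean the median SE was 1.05 and the share was 6.38%. Among the genes with a mean of 500 or more 0 passed (limma), with 158 at an unadjusted p under 0.05, 80 higher and 78 lower.

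**Figure D2:**
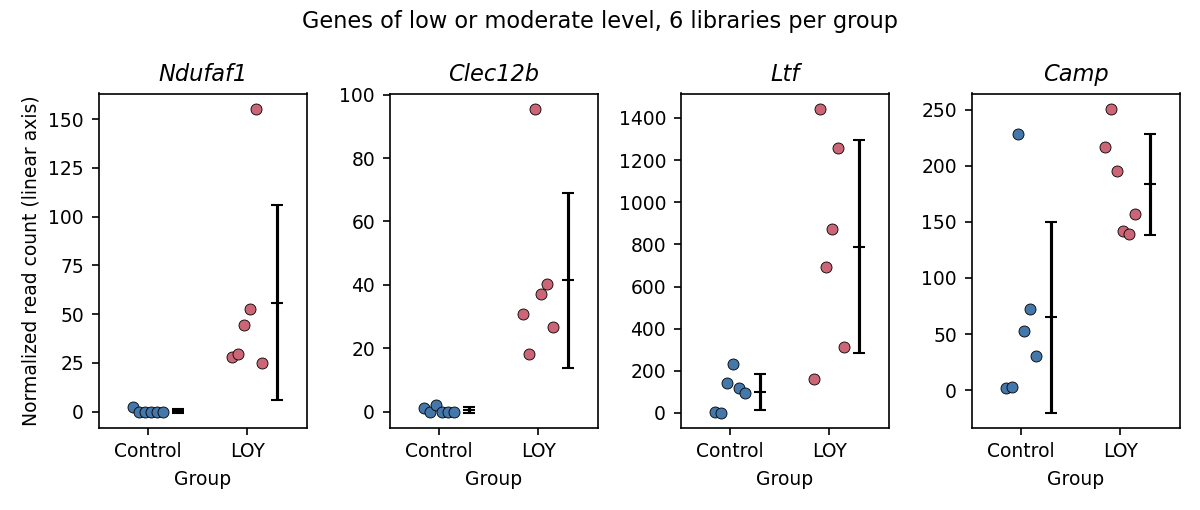
Normalized read counts (linear axes) of Ndufaf1, Clec12b, Ltf and Camp in the 6 control (blue) and 6 LOY (red) libraries, with the mean and SD in black. Ndufaf1 and Clec12b lie above every control library in all 6 LOY libraries, and Ltf does so in 5 of 6.

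Lists of neutrophil genes covered the maturation and function of these cells. Over all lists except the Y-linked one, 464 genes were tested with limma and 0 passed over all genes (28 at an unadjusted p under 0.05, 22 higher and 6 lower). With edgeR 0 passed as well (26 at an unadjusted p under 0.05). DESeq2 called 4, all higher: Ltf, Irf8, F13a1 and Ltbp1. The last 3 are named after their values were seen. Irf8 and F13a1 are in the monocyte and macrophage list and Ltbp1 in the TGF-beta and profibrotic list. F13a1 and Ltbp1 were above 0 in 2 LOY and 0 control libraries, so the limma filter left them out of the 464. Of the tested members of the granule lists, 6 primary, 17 secondary and 32 tertiary granule and mature neutrophil genes, 0 passed over all genes or adjusted over the list alone (limma), and the lists were not called (camera adjusted p = 0.799, 0.926 and 0.187). With the share of genes at 0 as a covariate, chosen after seeing the data, the secondary and tertiary lists were called higher (mean difference from other genes 0.48 and 0.37, camera adjusted p = 0.00867 for each). Without LOY 10 the tertiary list was called lower (−0.47, adjusted p = 0.0112). These calls use the preset correlation of 0.01, while the correlation estimated with all libraries and no covariate was 0.17 (secondary) and 0.269 (tertiary). Ltf, which encodes lactoferrin, stood at 99.3 ± 87.2 normalized reads in control and 790 ± 508 in LOY libraries (log2 fold change 3.84 ± 1.13 SE, limma adjusted p = 0.602). Camp, the cathelicidin gene, stood at 64.9 ± 84.8 and 184 ± 45.1 (2.78 ± 1.00) and lay above every control library in 1 of 6 LOY libraries. The authors' deposited log2 fold changes were 2.99 for Ltf and 1.499 for Camp. In Control 1 and 2 Ltf was at 6.45 and 1.28 normalized reads, against 96.3 to 232 in the other control libraries. Camp was at 2.15 and 2.56 in Control 1 and 2, against 30.6 to 229 in the other control libraries. The lysozyme gene Lyz2 stood at 262900 ± 52410 and 209700 ± 37510 (−0.32 ± 0.15). Of 22 migration and adhesion receptor genes 0 passed, with the formyl peptide receptor gene Fpr1 at −0.38 ± 0.14 and the selectin ligand gene Selplg at 0.18 ± 0.08 (camera adjusted p = 0.941). Of 20 NADPH oxidase and redox genes 0 passed (camera adjusted p = 0.926). Of 12 ageing and clearance genes 0 passed over all genes and 1 adjusted over the list alone, the clock repressor gene Cry2, at 51.3 ± 74.98 and 304 ± 157 normalized reads (4.31 ± 1.14), with Per2 at 2.66 ± 1.41 (camera adjusted p = 0.926). The authors' deposited log2 fold changes were 2.56 for Cry2 and 1.10 for Per2, and with the share of genes at 0 as a covariate Per2 was at −0.11. In Control 1, 2 and 12 Cry2 was near 0, at 1.08, 1.28 and 3.66 normalized reads, against 13.1 to 176 in the other control libraries. Its adjusted p in the authors' deposited table was 0.468.

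Inflammatory and profibrotic lists did not pass either. Of 25 NF-kB inflammatory genes 0 passed (camera adjusted p = 0.192), and the smallest p belonged to the chemokine gene Ccl4, at 821 ± 273 and 518 ± 161 normalized reads in control and LOY libraries (log2 fold change −0.65 ± 0.29 SE), followed by Bcl3 (−0.65 ± 0.30), Birc3 (−0.44 ± 0.21) and the interleukin 1 receptor antagonist gene Il1rn (−0.23 ± 0.13). Of 18 tested TGF-beta and profibrotic genes 0 passed with limma (camera adjusted p = 0.926), and Ltbp1, called by DESeq2, was not among them. In that list the transcriptional repressor gene Tgif1 stood at 421 ± 186 and 789 ± 219 (1.01 ± 0.35), the signal transducer gene Smad2 at 880 ± 298 and 1348 ± 257 (0.65 ± 0.23) and the receptor gene Tgfbr2 at 3076 ± 628 and 3641 ± 322 (0.26 ± 0.14). Of 38 interferon-stimulated genes 0 passed (camera adjusted p = 0.926), with Cxcl10 at 39.4 ± 57.2 and 53.6 ± 24.8 (2.60 ± 1.28, and 0.44 in the authors' deposited table) and Oasl1 at 0.39 ± 0.22. Without Control 1, 2 and 12 the Cxcl10 estimate was −0.03. Of 18 genes of MHC class I presentation 0 passed, with the peptide transporter gene Tap1 at 0.72 ± 0.27 (camera adjusted p = 0.941).

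The cell cycle list was higher in LOY (camera adjusted p = 0.024), while 0 of its 10 tested members passed over all genes and 1, the kinesin gene Kif23, when adjusted over the list alone. Its adjusted p was 0.222 with camera at an estimated correlation and 0.024 with fry. Of the 39 members of the list only 18 were in the table. Estimates were positive for 9 members and negative for 1, and the list median lay 0.634 above that of all genes. Kif23, which acts in cytokinesis, stood at 1498 ± 300 and 2201 ± 398 normalized reads (log2 fold change 0.56 ± 0.16 SE), the ubiquitin-conjugating enzyme gene Ube2c at 5.39 ± 11.2 and 83.3 ± 115 (3.75 ± 1.32), and the histone variant gene H2afz at 0.35 ± 0.17. Ube2c reached 313 in LOY 15, the library with the highest globin and Tfrc values, and 0 to 61.9 in the other LOY libraries. The replicative helicase gene Mcm7, at 0 in 2 control libraries, stood at 85.5 ± 104 and 146 ± 41.9 (2.68 ± 1.38, and 0.77 in the authors' deposited table). Pcna, named after its values were seen, had a positive estimate (1.70 ± 1.44) and a lower mean in LOY (141 and 131). Without Control 1, 2 and 12, the libraries with more genes at 0, the list was not called (adjusted p = 0.151). Its mean difference from other genes was then 0.70, against 0.80 with all libraries. With the share of genes at 0 as a covariate the call stood (0.79, adjusted p = 0.0176). The call ended with no low-value filter (0.38, adjusted p = 0.165) and with a mean of 50 or more (0.53, adjusted p = 0.0584). It also ended without Control 12 (adjusted p = 0.0727), Control 17 (0.0679), Control 18 (0.0569) or LOY 15 (0.149), and over all alternatives run the adjusted p ranged from 0.00534 to 0.222.

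Other biological lists showed no call with all 12 libraries. Of 16 p53 target genes 0 passed (camera adjusted p = 0.926), with Ei24 at 2.80 ± 1.15 and the death receptor gene Fas at 0.23 ± 0.17. Of 22 chromatin regulator genes 0 passed (camera adjusted p = 0.974), with the histone methyltransferase gene Ezh1 at 1438 ± 237 and 2303 ± 578 normalized reads (log2 fold change 0.66 ± 0.18 SE). Of 33 oxidative phosphorylation genes 0 passed (camera adjusted p = 0.179, and 0.023 without LOY 10, lower in LOY), with the complex II gene Sdhd at −0.34 ± 0.11 and the complex III gene Uqcrc1 at 0.66 ± 0.23. Of 23 glycolysis genes and 25 apoptosis genes 0 passed (camera adjusted p = 0.427 and 0.864). The quality lists of 23 immediate early and heat shock genes, 10 mitochondrially encoded genes and 49 ribosomal protein genes had 0 members past the threshold (camera adjusted p = 0.148, 0.164 and 0.137). The first was called lower without Control 1 (mean difference from other genes −0.70, adjusted p = 0.00652). The second was called lower without LOY 9 (−0.62, adjusted p = 0.0313) and the third without LOY 9 (−0.46, adjusted p = 0.0308) or LOY 10 (−0.50, adjusted p = 0.0112).

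Markers of other cell types were measured because a sort can carry other cells or their RNA. The erythroid list was higher in LOY (camera adjusted p = 0.0107), with 0 of 15 members past the threshold over all genes and 1, the transferrin receptor gene Tfrc, when adjusted over the list alone. Its adjusted p was 0.972 with camera at an estimated correlation and 0.509 with fry. Tfrc stood at 1.93 ± 4.22 and 62.2 ± 54.0 normalized reads (log2 fold change 4.51 ± 1.02 SE), Bnip3l at 0.34 ± 0.12, and Bpgm, a red cell glycolysis enzyme gene, at 676 ± 311 and 1494 ± 1234 (1.03 ± 0.43). The globin genes Hba-a1 (42860 ± 11910 and 86380 ± 79050) and Hbb-bs (25190 ± 5945 and 57300 ± 63730) were the most abundant, and Hbb-bt stood at 8846 ± 2410 and 20600 ± 22040. The 4 globin genes held 3.71% of normalized reads in the library of LOY 15 and 0.581% to 1.09% in the other LOY libraries, against 0.419% to 0.868% in control libraries (exact permutation test, two-sided p = 0.0844). Without LOY 15 the erythroid list had an adjusted p of 0.232, without Control 12 of 0.0727 and without Control 17 of 0.0608, in a range of 0.000218 to 0.972 over all alternatives run.

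Of the other cell type lists, B cells (12 tested members), monocytes and macrophages (9), dendritic cells and MHC class II (11) and platelets and megakaryocytes (14) had 0 members past the threshold (limma) and camera adjusted p of 0.926 each. In that order, estimates were positive for 8, 5, 6 and 8 members and negative for 4, 4, 5 and 6. The members with the smallest p were higher in LOY: Cr2 (log2 fold change 3.35 ± 1.47 SE), Csf1r (0.45 ± 0.19), Clec9a (3.84 ± 1.14) and F2rl2 (3.67 ± 1.37). Cr2, Clec9a and F2rl2 were at 0 in 3, 5 and 4 of 6 control libraries. With the share of genes at 0 as a covariate the B cell list was called lower (mean difference from other genes −1.56, adjusted p = 0.0116). That call uses the preset correlation of 0.01, while the correlation estimated for this list without the covariate was 0.379. Ighm stood at 4864 ± 1030 and 4173 ± 1911 normalized reads in control and LOY libraries, and Igkc at 546 ± 261 and 460 ± 415. Cd74 stood at 1780 ± 576 and 1614 ± 1249, and the platelet chemokine gene Pf4 at 414 ± 161 and 220 ± 93.1. Csf1r, the gene of CD115, for which the cells were sorted negative, stood at 9279 ± 2572 and 12440 ± 2295. It lay above every control library in 4 of 6 LOY libraries, and whether its reads came from monocytes was not tested. The T and NK cell list and the eosinophil and basophil list had 2 tested members each, too few for a list test. Cd3d stood at 137 ± 62.4 and 99.2 ± 55.9, Cd3g at 131 ± 99.3 and 39.7 ± 44.5, Hdc at 29300 ± 3983 and 25930 ± 4119, and Ccr3 at 58.3 ± 59.9 and 81.9 ± 50.6.

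**Figure D3:**
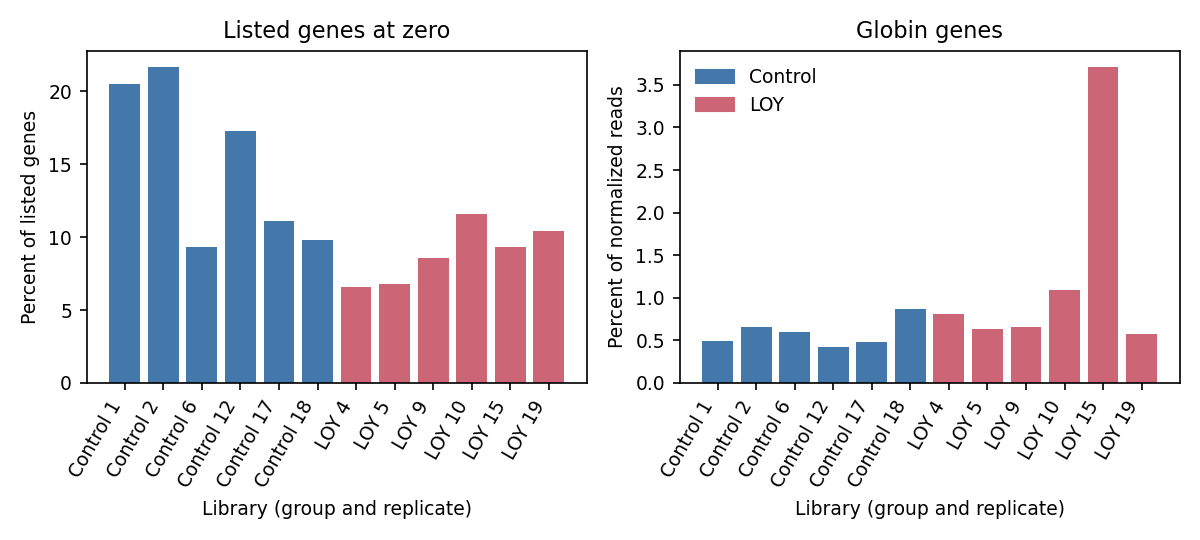
Percent of listed genes at 0 (left) and percent of normalized reads held by 4 globin genes (right) in each library, control in blue and LOY in red; bars start at 0. Control 1, 2 and 12 reach 20.5%, 21.7% and 17.3% of genes at 0, and LOY 15 reaches 3.71% for the globin genes.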

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

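The tests of the residual Y-linked reads, the erythroid list and the shift of the median gene were chosen after those results were seen, except the test of genes read in 1 control library alone, which was set before its result was seen. The counts of other splits of the libraries were planned, and their bounds were written down after the counts were seen. Of 198 groups of 6 libraries checked for a library far from the others, 26 showed one, where chance gives about 1 in 20, or 9.9.

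The library of LOY 4 lay far from the other LOY libraries in its Y-linked total, at 86.3 per 1000000 normalized reads against 0.162 to 6.73. A control library under that label is argued against, because the total was 39.8% of the control mean while the lowest control library was at 71.6%, more than 1 control SD (20.4%) higher. Reads carried over from 1 control library as the only source are argued against. The proportions of the 4 Y-linked list members in LOY 4 differed from those of each control library (permutation p of at most 0.00002 over 100000 resamples, against counting error alone). Uty stood at 1070% of Control 17 and Kdm5d at 0.0% of Control 6. Genes read in 1 control library alone met the limit set beforehand, a median under 9.94% of their level kept in LOY 4, for 5 controls (0.0% each, with only 3 such genes for Control 6) but missed it for Control 17 (14.5%, with 4 of 7 genes at 10% or more), so this test alone does not exclude that library. Reads from Control 17 along with another source of Y-linked reads stay open. Y-bearing cells among the sorted cells cannot be told apart from incomplete loss in this sample, RNA mixed in before amplification or reads from several control libraries, which stay open and untested, because each would give a ratio of Eif2s3y to Ddx3y in the control range of 1.18 to 3.85, as found (2.69).

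The library of LOY 15 lay apart in its globin total (3.71% of normalized reads against 0.581% to 1.09%), in the erythroid list (mean log2 value 12.7 against 9.26 to 10.4), and in Bpgm (11.97 against 9.57 to 10.18), Hbb-bt (15.99 against 13.14 to 13.95) and Hbb-bs (17.51 against 14.50 to 15.50). Erythroid RNA in the library of LOY 15 alone may account for the higher list, whose adjusted p was 0.232 without it and whose mean difference from other genes was then −0.00 against 0.49 with it. Erythroid RNA in every LOY library cannot be told apart from this: without LOY 15 the list mean less that of all tested genes differed by 0.0106 on the log2 scale, with a 95% interval (−0.70 to 0.72) that holds both 0 and 0.49, and Tfrc lay above every control library in 5 of 6 LOY libraries. Without LOY 15 the log2 globin share was 0.375 higher in LOY, with a 95% interval (−0.14 to 0.89) that holds 0. With all libraries the 95% intervals held 0 as well. They ran from −0.83 to 1.81 for the list difference of 0.49 and from −0.3 to 1.82 for the globin difference of 0.764. The red cell lysis and the gate would remove red cells, and a biological difference in LOY mice stays open and untested.

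The median gene was higher in LOY by 0.136 on the log2 scale. A candidate explanation is the larger number of zeros in the libraries of Control 1, 2 and 12: without these 3 the median was −0.0108, the lowest of the 20 ways to leave out 3 control libraries. A low rank was likely from the start, because zeros lower a control mean and these 3 were picked for having most zeros. The median was also near 0 with edgeR (−0.00993), DESeq2 (−0.0226), the zero-share covariate (−0.0389) and for genes with a mean of 500 or more (0.00151). The edgeR and DESeq2 normalizations centre fold changes near 0, and size factors centre well-read genes. The zero share itself differed between control and LOY libraries (means 14.95% and 8.88%), so its covariate takes up part of any group difference. These medians therefore cannot decide between the causes. An effect of LOY itself, on low genes or on the number of zeros, cannot be told apart from the zeros in Control 1, 2 and 12. The 3 libraries with most zeros are all controls. Other choices of 3 left-out controls gave medians from 0.0188 to 0.254, 9 of 19 above 0.1.

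The 2 genes and the 2 lists past the threshold were set against other splits of the 12 libraries. Of 100 splits, the real one included, 13 gave at least as many genes (real 2, highest other 7) and 55 at least as many lists (real 2, highest other 8), so chance cannot be excluded for either count. Every split with 3 or more genes had Control 1, 2 and 12 on the same side, as the real split has. Splits that parted these libraries gave at most 2 genes. The gene count therefore cannot be told apart from the placing of these libraries.

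Other libraries far from their group are given as log2(value + 1). In the mean over list members, LOY 19 stood at 11.6 for migration and adhesion receptors (others 11.93 to 12.04) and Control 1 at 10.39 for immediate early and heat shock genes (11.11 to 11.52). Among control libraries, Control 2 stood at 11.68 for Ddx3x, 2.28 for Zfx, 7.77 for Gm28329 (a chromosome Y pseudogene), 0.00 for Cd3g and 11.84 for Hist1h1c. Control 1 stood at 1.05 for Zrsr2, 1.66 for Ndufaf1 (the others at 0) and 6.21 for Igkc. Control 6 stood at 4.87 for Tnfrsf12a (the others at 0) and 6.18 for Il1rl1 (0.00 to 1.52), Control 18 at 3.52 for Tfrc and Control 17 at 5.16 for Cd3d. Among LOY libraries, LOY 4 stood at 10.52 for Slc39a4, LOY 5 at 9.74 for Smad2, LOY 9 at 13.62 for Fpr1 and 3.05 for Cd3d, LOY 15 at 2.19 for Ccr3 and LOY 19 at 1.45 for Tfrc.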

How the results depend on the processing

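No paired analysis was possible because the groups share no replicate number. The settings chosen after seeing the data were a mean of 500 or more, the share of genes at 0 as a covariate, the joint removal of Control 1, 2 and 12, edgeR without Control 6, and 2 member choices for the Y-linked total; where a value moved, the cause was not tested. The Y-linked total was lower in LOY under every alternative run (−215.1 to −193.7 per 1000000 normalized reads with 1 library left out). Normalizations by 1 factor per library leave it as it is. Of the X-linked homologues 0 passed over the list alone in every alternative run. The count of genes, 2, was 54 with DESeq2, 1 with sample weights, 0 with edgeR (with or without Control 6), quantile normalization, a mean of 50 or of 500 or more, 1 surrogate variable, the zero-share covariate, or without Control 1, 2 and 12, and 0 to 17 with 1 library left out. The count of lists, 2, was 1 with no filter, a mean of 50 or of 500 or more, or fry, 0 with an estimated correlation or without Control 1, 2 and 12, 5 with the zero-share covariate, and 0 to 5 with 1 library left out. A change of sign was counted only where the main value lay more than 1 SE from 0 or the alternative passed the threshold. With the zero-share covariate the values were −0.24 for Zfx, −0.07 for Cxcl10, −0.11 for Per2 and −1.21 for Ccr3, and for lists, as mean differences from other genes, 0.0404 for NF-kB, 0.48 for secondary and 0.37 for tertiary granules, 0.0854 for glycolysis, 0.0659 for oxidative phosphorylation, 0.17 for mitochondrially encoded, 0.0579 for ribosomal proteins and −1.56 for B cells. With quantile normalization they were 0.0559 for NF-kB, 0.0391 for tertiary granules, 0.0505 for glycolysis, 0.0336 for oxidative phosphorylation, 0.00391 for ribosomal proteins and −0.000231 for Ccr3. With 1 surrogate variable they were −0.0103 for Zfx, −0.19 for Ccr3, 0.13 for tertiary granules and 0.0303 for mitochondrially encoded genes. Without Control 1, 2 and 12 they were −0.0316 for Cxcl10, −1.02 for Ccr3, 0.12 for NF-kB, 0.22 for tertiary granules and 0.0157 for glycolysis. With 1 library left out the erythroid list ranged from −0.0039 (without LOY 15) to 0.69 (without LOY 9). Of 66 named genes 44, and of 25 lists 2, kept sign and side in all alternatives run.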

Other observations

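The following genes were chosen after their values were seen. Il1rl1, the receptor gene of interleukin 33, stood at 12.7 ± 28.8 normalized reads in control and 91.2 ± 32.5 in LOY libraries (SD, n = 6 each; log2 fold change 4.75 ± 0.98 SE, limma adjusted p = 0.276). Among the control libraries it was high in that of Control 6 alone, without which its adjusted p was 0.00592. The transcriptional repressor gene Klf3 stood at 3432 ± 281 and 4657 ± 583 (0.44 ± 0.10, adjusted p = 0.332) and the linker histone gene Hist1h1c at 4479 ± 428 and 5480 ± 384 (0.29 ± 0.09, adjusted p = 0.602), both higher in 6 of 6 LOY libraries than in any control library. Of the tested genes 17 had every LOY library above every control library and 11 the reverse, where chance gives 0.216% of genes, or 21.1.

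The authors' deposited table gives no p for Ddx3y, Eif2s3y or Il1rl1, while a DESeq2 refit of the recovered reads gave unadjusted p of 0.00159, 0.00687 and 0.0248. The largest Cook's distance, a measure of how far 1 library moves a fit, was 8.39 and 8.44 at LOY 4 for Ddx3y and Eif2s3y and 9.94 at Control 6 for Il1rl1, above a limit of 7.56. In the authors' deposited table Kdm5d had an adjusted p of 9.88e-11, with 2 control libraries above 0. Among the genes that table calls, the top 2 libraries of the higher group held a median of 70.1% of that group's total.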
